A study of Drosophila melanogaster with 24 samples.

How the data were processed

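The data are normalized intensities from Affymetrix Drosophila Genome 2.0 arrays, 24 arrays in 8 groups of 3. The authors' processing notes name GCRMA and MAS5 for the deposited values, without versions and without saying which step each served. The deposited values are linear, although a GCRMA value is often given as a log, and 48.3% of them lie at a floor of 4.51. Per the labels, S2 cells were treated with dsRNA against eater or with irrelevant control dsRNA, cooled, given heat-inactivated fluorescent bacteria on ice or none, and warmed to 26.5 °C. Complete replicate sets were processed in parallel, so the replicate number joins arrays across groups. Same-number arrays of different groups correlated over 0.1 in 77 of 84 pairs of residuals (median 0.45), against a median of -0.31 for other numbers, and the first residual component (48.4% of the residual variance) set replicate 3 apart.

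Of 18952 probe sets, 183 control probe sets were left out of the comparisons. The other 18769 comprised 13647 with 1 gene symbol, 402 with several and 4720 with none. Where a gene had several probe sets, the one with the highest mean was kept, which left 17104 features, 11982 of them with a symbol. Of these, 4677 had the same value on all arrays. A planned filter at the 40th percentile removed nothing, because that percentile was the floor itself. Intensities were log2 transformed after adding 16, so log2 changes of genes near the floor are drawn towards 0.

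A linear model of 8 group means (16 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all features of a comparison. The prior degrees of freedom came to 0.265, so the variance of each gene rests almost wholly on its own arrays. A feature was called at an adjusted p below 0.05. The comparisons, 15 in all, were the response to bacteria at each time in each knockdown, eater RNAi against control RNAi in each condition and on average, and the difference between the responses at each time and at any time. A fit with the replicate as a block has 14 residual degrees of freedom. In each knockdown the only group without bacteria was taken at 30 min. Responses at 90 and 180 min therefore join the effect of bacteria with that of time after warming.

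Gene lists were fixed before the data were examined, as were the model, the comparisons, the thresholds, the alternatives tried and the rule for naming genes. They cover antimicrobial peptides, the Imd, Toll, JNK and JAK/STAT pathways, phagocytic receptors, actin regulators, endosome and phagosome trafficking, lysosome and vacuolar ATPase, heat shock, ER stress, oxidative stress and detoxification, small RNA and antiviral defence, cell cycle and DNA replication, ribosome biogenesis, ribosomal proteins, the proteasome, glycolysis, oxidative phosphorylation, apoptosis, autophagy, coagulation and melanization, early growth response, and markers of plasmatocytes, lamellocytes, fat body, muscle and germ line. A list needed 5 measured members; the markers of crystal cells and a list of reference genes fell short and were not tested. Members not matched by name to a probe set here, 129 in all, were left out; they include AttA, Dpt and PGRP-LC. Each list was compared with all other features by camera in limma with an inter-gene correlation of 0.01, adjusted over 392 tests (28 lists in 14 comparisons). Of 123 list calls, 31 also passed with the correlation estimated from the data and 66 with fry. Over all 392 tests fry gave 85 calls.

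In each comparison the named genes are eater, the 8 called features with the highest and the 8 with the lowest log2 change among those with 1 symbol whose arrays did not overlap between the groups, and up to 4 members of each list with a called member (2 otherwise), taken by adjusted p. For the average over conditions, the 4 differences had to share 1 sign in place of the overlap condition. A gene named outside this rule was chosen after its values were seen, and this is said where it occurs.

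The steps were tested on simulated data of the same size, with 50 genes changed at each fold change. The changed genes had a mean intensity of at least 100. Noise was independent between features and arrays, unlike the residuals of the real arrays. The results may therefore not hold for weaker features or correlated lists. For the response at 180 min, 36% of the changed genes were called at a 1.25-fold change, 80.0% at 1.5-fold and 98.0% at 2-fold. For the difference of responses the shares were 20.0%, 56.0% and 88.0%. For eater RNAi against control RNAi without bacteria they were 52%, 72% and 96%. False calls among the unchanged features numbered 4, 9 and 7, in data of 17104 features in all. The simulated data held many changed genes, so these counts cannot be set against the number of calls in the real data. The camera p of an unchanged list was 0.988, 0.249 and 0.545. Deposited control probe sets gave 3' to 5' ratios of 2.15 to 2.56 for actin, 0.883 to 1.12 for GAPDH and 2.24 to 3.42 for eIF4A. The number of arrays limits the precision of every comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.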

Results

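Transcript levels were measured on 24 arrays of Drosophila S2 cells, a phagocytic line derived from hemocytes. Cells treated with dsRNA against eater, which encodes a phagocytic receptor, or with irrelevant control dsRNA were left without bacteria for 30 min or given heat-inactivated Staphylococcus aureus and Serratia marcescens for 30, 90 or 180 min, with 3 arrays in each of 8 groups. Phagocytosis in parallel samples was 50 to 80% lower after eater RNAi, per the labels. The mean intensity was 944 to 964 per array, and 6374 to 6603 probe sets had an intensity over 100. Log2 changes below are of the intensity plus 16, with the SE of the fitted change; means are of 3 arrays with SD unless another n is given.

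In every condition eater fell to 4.05 to 6.22% of its level in control RNAi. The knockdown is the basis for every comparison between the dsRNAs. Without bacteria eater had a mean intensity of 2788 ± 184 in control RNAi and 164 ± 26.5 in eater RNAi (n = 3 each). With bacteria the means were 2900 ± 191 and 117 ± 5.95 at 30 min, 2038 ± 17.4 and 127 ± 1.61 at 90 min, and 2116 ± 96.7 and 129 ± 10.3 at 180 min. The 12 control arrays ranged from 2019 to 3094 and the 12 eater RNAi arrays from 112 to 187. The log2 difference over the 4 conditions was -4.04 ± 0.04 (limma adjusted p = 1.24e-19). In control RNAi, eater itself fell with bacteria by 0.45 at 90 min (adjusted p = 0.0019) and by 0.39 at 180 min (adjusted p = 0.0038).

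**Figure D1:**
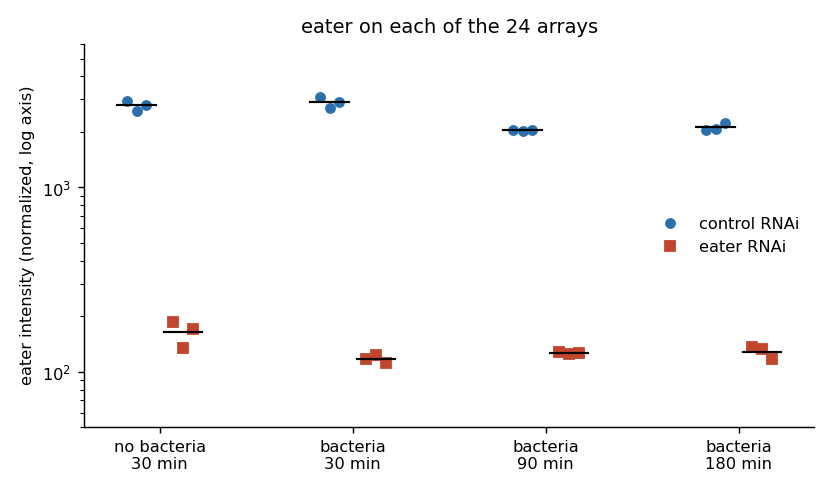
Intensity of eater on each array by condition, control RNAi and eater RNAi, with 1 point for each replicate (3 per group). The axis is logarithmic and does not start at 0. The control arrays lie between 2019 and 3094 and the eater RNAi arrays between 112 and 187.

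Within 30 min of warming, control RNAi cells with bacteria had higher levels of Imd and JNK pathway transcripts, and of 5 of 17 antimicrobial peptide transcripts, than cells without bacteria. This comparison, the only one matched in time among the responses in control RNAi, asks which genes respond first. Transcripts of pirk, which encodes a negative regulator of Imd signalling, rose from 1140 ± 1437 to 10359 ± 531, a log2 change of 4.09 ± 0.79 (adjusted p = 0.00587). Replicate 2 was high before bacteria, at 2787 against at most 493 in the others, and without it the change was 5.16 for pirk, 3.75 for Mtk (3.01 with it) and 3.29 for edin (2.65 with it), while AttD lost its call (2.33, adjusted p = 0.116). The serine protease homologue gene scaf, a JNK target, rose from 391 to 3784 ± 465 (3.24 ± 0.18, adjusted p = 1.51e-08). Rel, the NF-kappaB factor of the Imd pathway, rose from 4208 to 13947 (1.76 ± 0.16, adjusted p = 3.87e-06). Among genes given by the naming rule, the largest falls were in CG8668, from 4581 ± 162 to 2026 ± 123 (-1.17 ± 0.09), and in the replication origin gene Orc1 (-0.99 ± 0.19).

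Of 17 antimicrobial peptide genes, 5 rose at 30 min and 0 fell (6 rose adjusted over the list alone): Mtk (3.01 ± 0.52), edin (2.65 ± 0.43), CecB (2.62 ± 0.36), Drs (2.18 ± 0.22) and AttD (2.11 ± 0.33). The camera test of the list gave an adjusted p of 4.08e-05, and 0.0865 with an estimated correlation; the list median was 0 and its mean 0.78. Of 21 Imd pathway genes 5 rose and 0 fell (6 rose adjusted over the list alone; camera adjusted p = 1.46e-06), among them PGRP-LF (1.13), Dredd (0.30) and Fadd (0.22). Of 19 JNK genes 5 rose (7 adjusted over the list alone; camera adjusted p = 5.15e-07), with Ets21C at 2.44 ± 0.31, the phosphatase gene puc at 1.31 ± 0.09 and Jra, the fly Jun, at 0.90 ± 0.04. Of 19 Toll pathway genes 4 rose, including Tollo (2.83-fold) and dl (0.36), with camera adjusted p = 0.0135 (0.071 with an estimated correlation). Early growth genes rose in 5 and fell in 1 of 16 (camera adjusted p = 0.00119). Apoptosis genes rose in 3 of 11 (camera adjusted p = 0.00363), among them the caspase gene Dronc (0.52 ± 0.09). Lamellocyte markers rose in 3 of 8 (camera adjusted p = 1.22e-08). The lamellocyte list shares msn and puc with the JNK list, and puc is among its 3 genes that rose, so the 2 calls are not separate. These calls for the Imd, JNK, early growth, apoptosis and lamellocyte lists are the 5 of 12 at this time that held with an estimated correlation.

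Single genes of other lists rose or fell as well at 30 min. The cytokine gene upd2 rose by 1.33 ± 0.12 and the thioester protein gene Tep4 by 0.75, and 2 of 15 JAK/STAT genes rose (camera adjusted p = 0.22). The antiviral gene vir-1 rose by 1.62 ± 0.26, alone among 11 small RNA and antiviral genes. Actin regulators rose in 2 of 21, with cpa at 0.21 and Arpc4 at 0.20 (camera adjusted p = 1.90e-06, and 0.154 with an estimated correlation). Trafficking genes rose in 2 of 28, with Rbsn-5 at 0.44 and Exo84 at 0.22 (camera adjusted p = 0.00586, and 0.24 with an estimated correlation). Cell cycle genes were lower as a list with 1 of 18 called (camera adjusted p = 5.85e-09, and 0.228 with an estimated correlation), as were ribosome biogenesis genes with 2 of 28 called, l(3)72Dn (-0.20) and Ns3 (-0.18) (1.61e-04, and 0.369 with an estimated correlation). Among heat shock genes stv rose by 0.97 ± 0.24, 1 other rose and DnaJ-1 fell by 0.47 ± 0.09. In all, 446 of 17104 features were called, 356 higher and 90 lower, 53 and 2 of them by at least 2-fold. With the replicate as a block the count was 775, without replicate 1 or 2 it was 142 or 109.

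By 90 min, transcripts of several antimicrobial peptides were more than 16 times their level without bacteria. This comparison and the next use the 30 min cells without bacteria, so bacteria and time after warming cannot be told apart in them. AttD rose from 97.8 ± 39.5 to 6437 ± 764 (5.89 ± 0.33, adjusted p = 3.50e-09) and DptB from 275 ± 98.6 to 4823 ± 314 (4.11 ± 0.25, adjusted p = 9.05e-09). DptB had not passed the test at 30 min (0.71 ± 0.25, adjusted p = 0.231). The amidase gene PGRP-LB, whose product degrades peptidoglycan, rose by 2.47 ± 0.18 and scaf by 4.30 ± 0.18. The sugar transporter gene Slc45-1 fell (-1.98 ± 0.27), as did Reck (-1.66 ± 0.14) and the hexokinase gene Hex-A (-1.39 ± 0.22).

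Of 17 antimicrobial peptide genes 6 rose at 90 min and 0 fell (6 rose adjusted over the list alone; camera adjusted p = 4.94e-07), led after AttD by edin (5.41), Mtk (5.31) and Drs (4.66). Of 21 Imd genes 11 rose and 0 fell (camera adjusted p = 7.94e-11), from Rel (2.18), PGRP-LF (1.91) and PGRP-SB1 (1.33) to imd (0.41), key (0.34), Charon (0.30) and Diap2 (0.24). JNK genes rose in 5 and fell in 1 of 19, with Jra at 0.96 and Gadd45 at 0.91 (camera adjusted p = 0.0197; 0.194 with an estimated correlation and 0.0966 with the replicate as a block). Actin regulators rose in 5 of 21, with the formin gene capu at 2.09-fold, Arpc2 at 0.38 and cpb at 0.26 (camera adjusted p = 5.20e-07, and 0.128 with an estimated correlation). Trafficking genes rose in 7 of 28, among them Sec10 (0.46), Snap24 (0.42) and Rab14 (0.31) (camera adjusted p = 0.0113, and 0.285 with an estimated correlation). Lamellocyte markers rose in 3 of 8 (camera adjusted p = 5.20e-07), and apoptosis genes in 3 of 11 (0.0117, and 0.071 with an estimated correlation).

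Among the lists that were lower at 90 min, the plasmatocyte markers alone held with an estimated correlation. Lysosome and vacuolar ATPase genes fell in 6 and rose in 2 of 28, with Hexo2 at -0.43 and Vha44 at -0.37 (camera adjusted p = 0.00275, and 0.134 with an estimated correlation). Plasmatocyte markers fell in 3 of 12, including ush, a cofactor of GATA factors, at -0.84 ± 0.15, and Sr-CI at -0.49 (camera adjusted p = 0.00155, kept with an estimated correlation, and passed also without eater). Glycolysis genes fell in 2 of 11 (camera adjusted p = 0.00276, and 0.485 with an estimated correlation), oxidative phosphorylation genes in 5 of 71 (0.00275, and 0.667 with an estimated correlation), and cell cycle genes in 4 of 18, among them aurB (-0.37), Mcm6 (-0.31) and Mcm2 (-0.28) (1.69e-04, and 0.506 with an estimated correlation). Toll genes went both ways, with pll (0.54) and cact (0.32) up and spz (-0.37) and grass (-0.39) down (camera adjusted p = 0.278). The count was 1359 of 17104, 725 higher and 634 lower (82 and 32 by at least 2-fold); it was 2210 with the replicate as a block and 556 or 423 without replicate 1 or 2.

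At 180 min several antimicrobial peptide transcripts were higher still, while lysosomal genes as a group and single receptor and sugar metabolism genes were lower than in cells without bacteria. AttD reached 22991 ± 1505 (7.73 ± 0.33, adjusted p = 1.34e-10), edin 34158 ± 2737 (6.65 ± 0.43) and PGRP-LB 1180 ± 132 from 17.6 ± 4.28 (5.15 ± 0.18, adjusted p = 2.21e-11). The glutamine synthetase gene Gs1 fell from 5075 ± 564 to 1048 ± 82.0 (-2.25 ± 0.10, adjusted p = 2.52e-10), Sirup, which serves assembly of respiratory complex II, by 2.35 ± 0.31 and Slc45-1 by 2.47 ± 0.27. The JNK phosphatase gene puc, raised at 30 min, lay below its level without bacteria (-0.67 ± 0.09, adjusted p = 3.66e-05).

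Antimicrobial peptide genes rose in 6 of 17 at 180 min (camera adjusted p = 3.59e-08; mean 2.16, median 0), including Mtk (6.25), Drs (6.20), DptB (6.06) and CecB (3.94). Imd genes rose in 10 and fell in 1 of 21 (camera adjusted p = 2.35e-08): PGRP-SB1 (3.67), Rel (1.83) and Charon (0.92) rose, and Uev1A fell (-0.18). Toll genes rose in 3 and fell in 5 of 19: cact, which encodes the pathway's inhibitor, rose by 0.97 ± 0.08, while grass (from 1993 to 945), Tl (-0.80, its other probe set not called), spz (-0.54) and dl (-0.23) fell (camera adjusted p = 0.496). Phagocytic receptor genes fell in 4 and rose in 1 of 28 (camera adjusted p = 0.0185, and 0.0848 with an estimated correlation). Among them NimC4 fell from 177 ± 13.6 to 64.1 ± 8.73 (-1.27 ± 0.11) and drpr, the receptor for dying cells, by 0.60 ± 0.07. Lysosome and vacuolar ATPase genes fell in 11 and rose in 1 of 28 (camera adjusted p = 1.49e-07, kept with an estimated correlation), with the lysosomal carrier gene spin at -0.83 ± 0.08, VhaSFD at -0.45 and Vha44 at -0.45. Plasmatocyte markers fell in 3 and rose in 1 of 12, with ush going from 4392 ± 574 to 2176 ± 207 and Hml at 0.72 (camera adjusted p = 0.00363, and 0.071 with an estimated correlation).

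Ribosome biogenesis genes rose in 17 and fell in 1 of 28 at 180 min (21 and 3 adjusted over the list alone; camera adjusted p = 1.02e-10, and 0.0865 with an estimated correlation), with l(3)72Dn at 0.54 ± 0.05, CG11920 at 0.49 and Ns3 at 0.38. Cell cycle genes rose in 4 of 18, with Mcm3 (0.47), pim (0.41), PCNA (0.32) and Mcm2 (0.28) (camera adjusted p = 0.00103, and 0.574 with an estimated correlation). Glycolysis genes fell in 3 of 11, with the trehalose transporter gene Tret1-1 at -1.36 ± 0.14, Hex-A at -1.50 ± 0.22 and the aldolase gene Ald1 at -0.58 (camera adjusted p = 1.38e-06, and 0.209 with an estimated correlation). Heat shock genes rose in 4 of 12, among them Hsp68 (0.93), DnaJ-1 (0.76 ± 0.09) and Hsp27 (0.40) (camera adjusted p = 0.0995). ER stress genes fell in 2 of 18, Herp (-0.38) and crc (-0.33) (camera adjusted p = 0.0123, and 0.654 with an estimated correlation). Early growth genes fell in 4 and rose in 1 of 16 (0.0255, and 0.114 with an estimated correlation), with edl at -1.26 and Mkp3 at -0.43. Actin regulators rose in 5 and fell in 3 of 21 (camera adjusted p = 0.0491, and 0.624 with an estimated correlation). Of 17104 features 1142 were higher and 769 lower, 90 and 91 by at least 2-fold. The total of 1911 was 1079 or 695 without replicate 1 or 2.

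**Figure D2:**
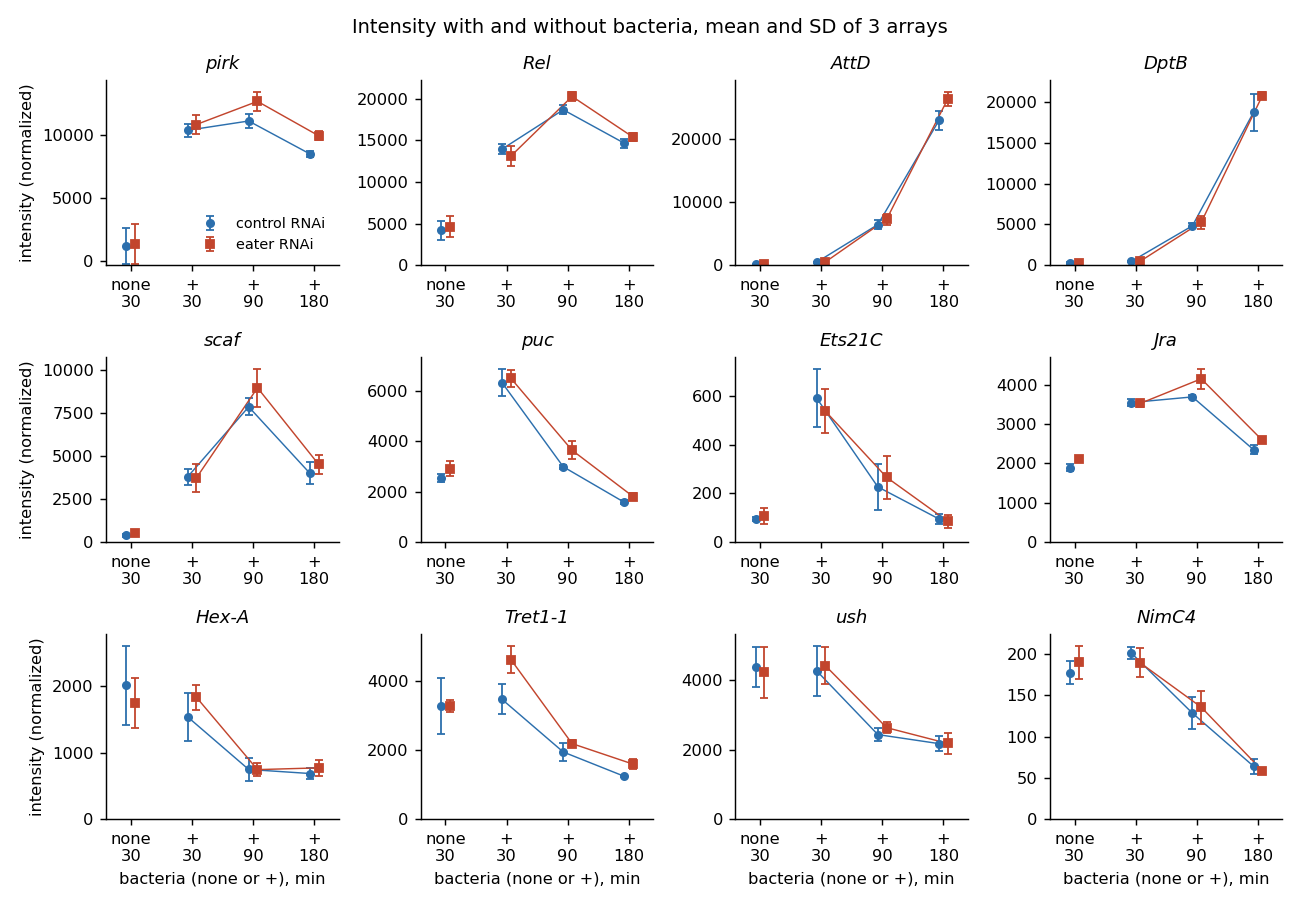
Intensity (linear axis) of 12 genes without bacteria at 30 min and with bacteria at 30, 90 and 180 min, mean and SD of 3 arrays, in control RNAi and eater RNAi. The genes are those named in the text for their course; AttD reached 22991 at 180 min in control RNAi, whereas puc was at 6318 at 30 min and 1577 at 180 min.

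After eater RNAi the response at 30 min began with the same genes. The comparison asks whether cells with less eater still respond. Transcripts of pirk rose by 3.76 ± 0.79, Mtk by 3.08, scaf by 2.82, edin by 2.47, CecB by 2.26 and Drs by 2.18, and CG8668 (-0.96) and Orc1 (-0.92) fell. Imd genes rose in 4 of 21 (8 adjusted over the list alone; camera adjusted p = 1.38e-07), with Rel at 1.53. JNK genes rose in 6 and fell in 1 of 19 (camera adjusted p = 1.03e-08), with Ets21C at 2.17, puc at 1.16, Gadd45 at 1.05 and Jra at 0.73, and antimicrobial peptide genes rose in 5 of 17 (2.36e-05, and 0.0791 with an estimated correlation). Ribosome biogenesis genes fell in 4 of 28 (14 adjusted over the list alone; camera adjusted p = 1.64e-09, and 0.112 with an estimated correlation). The count was 464, 282 higher and 182 lower, and 992 with the replicate as a block. It was 102 without replicate 1, 153 without replicate 2, 268 without the eater RNAi array of replicate 1 lacking bacteria and 282 without the 30 min eater RNAi array of replicate 3.

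At 90 and 180 min the eater RNAi cells had the same leading genes as control RNAi cells. AttD rose by 5.90 at 90 min and 7.76 at 180 min, edin by 5.39 and 6.69, Drs by 4.56 and 6.23, DptB by 4.13 and 6.12, and PGRP-LB by 5.41 at 180 min. Imd genes rose in 11 of 21 at 90 min (camera adjusted p = 7.94e-11) and rose in 11 and fell in 1 at 180 min (6.25e-10). Slc45-1 fell at 90 min (-2.11) and 180 min (-2.41), and Gs1 (-2.08), Sirup (-2.69), NimC4 (-1.46), Hex-A (-1.14) and Tret1-1 (-1.03) at 180 min. Lysosome genes fell in 9 of 28 at 180 min (camera adjusted p = 5.20e-07, kept with an estimated correlation). Cell cycle genes fell in 9 of 18 at 90 min, among them Orc2 (-0.63), dup (-0.52), Mcm2 (-0.48) and Mcm3 (-0.48) (camera adjusted p = 5.98e-08, and 0.262 with an estimated correlation). Counts were 751 higher and 1097 lower at 90 min and 847 higher and 874 lower at 180 min. The totals of 1848 and 1721 were 2870 and 2584 with the replicate as a block, 589 or 636 at 90 min and 761 or 555 at 180 min without replicate 1 or 2.

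The genes that responded in control RNAi responded with similar size after eater RNAi at 90 and 180 min, and less certainly so at 30 min. The question is whether eater RNAi weakened the transcriptional response to bacteria. Across features called in either knockdown the log2 responses correlated at r = 0.964 at 30 min (631 features) and r = 0.973 at 90 min (2096) and at 180 min (2324); over all 12427 features that were not constant r was 0.821, 0.936 and 0.932. Of the features called higher, 234 were shared at 30 min, 594 at 90 min and 714 at 180 min. Independent lists of these sizes among all 17104 features would share 5.87, 31.8 and 56.6. Of the features called lower, 45, 517 and 594 were shared, against 0.958, 40.7 and 39.3. The 4677 constant features can never be called, so these expected numbers are too low. For features whose response averaged over both knockdowns was at least 2-fold, the log2 responses were summed. The percentages are therefore not shares of transcript amount. The sum in eater RNAi was 91.3 ± 10.9% of that in control RNAi at 30 min (59 features, with 86.3, 83.9 and 103.9% in the replicates). It was 101.8 ± 0.727% at 90 min (122) and 103.4 ± 2.45% at 180 min (181), each with the SD of 3 replicates. The median difference along the response was -0.18 at 30 min, 0.02 at 90 min and 0.04 at 180 min.

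Tested directly, the difference of response at each time had 1 call of 17104, the same gene each time, CG14275, with differences of less than 0.01 at an intensity near the floor (limma; unadjusted p was below 0.05 for 464, 317 and 428 features). Leaving out arrays gave up to 16 calls at 30 min (without the 30 min eater RNAi array of replicate 2), 8 at 90 min (without the no-bacteria eater RNAi array of replicate 2) and 12 at 180 min (without replicate 1). For AttD at 180 min the difference was 0.03 (95% interval -0.95 to 1.02), for DptB 0.06 (-0.67 to 0.80), for Drs 0.03 (-0.64 to 0.70), and for PGRP-LB 0.26 (-0.27 to 0.79). For PGRP-SB1 it was 0.66 (paired 95% interval 0.13 to 1.18, n = 3), with 0.90, 0.51 and 0.56 in the replicates, a larger rise after eater RNAi that did not pass after adjustment over all features (adjusted p = 1). For some other genes the unadjusted 95% interval from the fit, which does not pair the replicates, excluded 0. It did so in both directions, and none of these genes passed after adjustment. Among them, chosen after their values were seen, were retm at 30 min (0.48, 0.10 to 0.86) and jigr1 at 90 min (-0.46, -0.84 to -0.09). Snoo at 180 min was another (0.39, 0.10 to 0.68). Their paired 95% intervals included 0 (n = 3): -0.04 to 0.99 for retm, -1.04 to 0.11 for jigr1 and -0.20 to 0.98 for Snoo. At 30 min the difference was -0.42 (-0.97 to 0.13) for scaf and -0.33 for pirk. The wide interval for pirk (-2.70 to 2.03) comes from cells without bacteria, high in replicate 2 of both knockdowns; within the replicates its differences were -0.80, -0.18 and -0.03 (paired 95% interval -1.34 to 0.67, n = 3), and those of scaf -0.90, -0.90 and 0.54 (-2.48 to 1.64), so a weakening of these early responses is not excluded. The median distance from the estimate to either end of such intervals was 0.63, 0.53 and 0.56 at the 3 times. Among lists, 13 differences passed camera and 0 of them with an estimated correlation: at 30 min oxidative phosphorylation (adjusted p = 1.46e-06, estimated 0.46), glycolysis (0.00116, estimated 0.445), ribosome biogenesis (0.00661, estimated 0.569), trafficking (0.00811, estimated 0.26), lysosome (0.0185, estimated 0.24) and proteasome (0.0477, estimated 0.511). At 90 min they were cell cycle (0.00112, estimated 0.575), ribosome biogenesis (0.0299, estimated 0.654), apoptosis (0.0338, estimated 0.114) and coagulation (0.0338, estimated 0.23), and at 180 min cell cycle (0.00161, estimated 0.589), glycolysis (0.00598, estimated 0.526) and oxidative phosphorylation (0.0299, estimated 0.761).

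**Figure D3:**
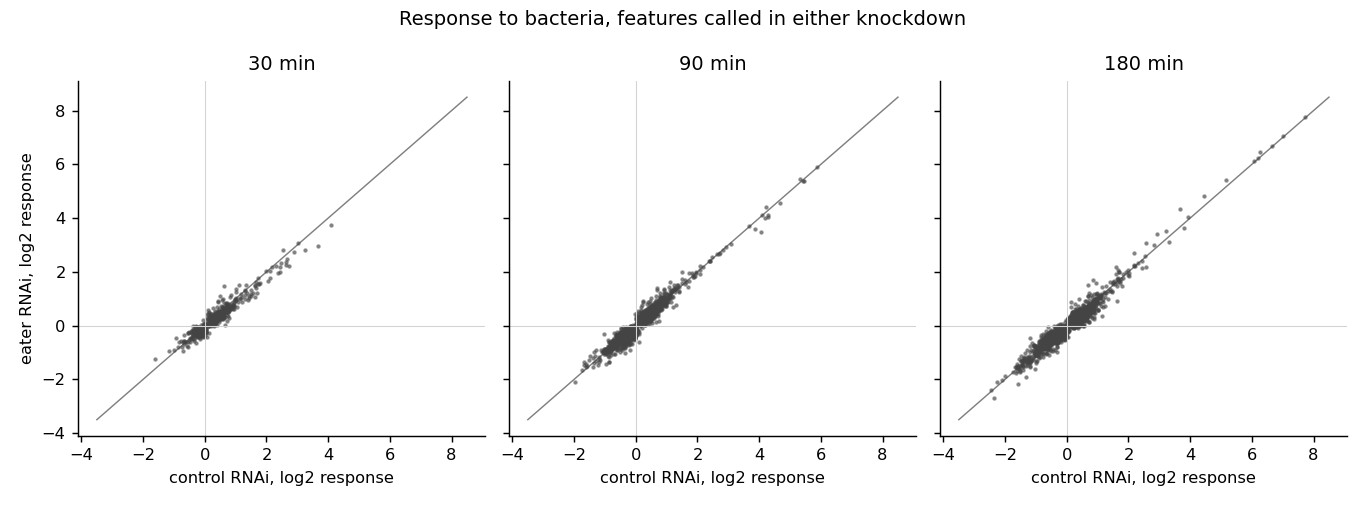
Log2 response to bacteria in eater RNAi (vertical) against control RNAi (horizontal) at 30, 90 and 180 min; each point is a feature called in either knockdown and the grey line marks equal responses. Points lie along the line, with r = 0.964, 0.973 and 0.973.

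Apart from eater itself, RNAi against eater went with small differences in single genes, the largest of them in Nazo, Sec24AB and Drs. The comparison averages the 4 conditions (12 arrays against 12). Sec24AB, a COPII coat gene, fell from a mean of 1873 to 1191 (-0.64 ± 0.04, adjusted p = 3.36e-08). Stam, whose product sorts ubiquitinated cargo on endosomes, fell from 4833 to 3415 (-0.51 ± 0.03, adjusted p = 5.17e-08), and its partner in that complex, Hrs, fell by 0.32 ± 0.04 (adjusted p = 0.00121). Hem, a subunit of the SCAR/WAVE complex that drives actin branching, fell from 2823 to 2199 (-0.36 ± 0.02, adjusted p = 2.66e-08), the vinculin gene Vinc by 0.30 ± 0.03, the endocytic recycling gene Past1 by 0.30 ± 0.05 and CG16721 by 0.51 ± 0.05. Higher after eater RNAi were Nazo (0.67 ± 0.13), Drs (0.52 ± 0.11, adjusted p = 0.0451), corto (0.37), the tetraspanin gene Tsp42Ef (0.36 ± 0.04), Tsf3 (0.35), Rab40 (0.34), CG13258 (0.34), CG8353 (0.32) and the translation factor gene eIF4A (0.19 ± 0.01). Apart from eIF4A, a member of the reference list, these are the 15 genes besides eater that the naming rule gives by size. All 15 differed in the same direction in all 3 replicates, but the same arrays served to choose them, so this is no separate test.

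The count was 99 features, 70 higher and 29 lower, and no feature other than eater differed by 2-fold; the share that was higher was 70.7%, or 46.7% with quantile normalization. It was 583 with the replicate as a block, 19 and 10 without replicate 1 or 2, 392 without replicate 3, 165 without the control array of replicate 3 lacking bacteria, 65 without the 30 min control array of replicate 2, and 55 and 59 without the 90 min eater RNAi arrays of replicates 1 and 2. Actin regulators as a list did not pass, with 1 of 21 higher and Hem lower (camera adjusted p = 0.467). Trafficking genes, which do not include Stam, Hrs or Past1, were higher as a list with 0 of 28 called (3 adjusted over the list alone; camera adjusted p = 4.60e-07, kept with an estimated correlation), germ line markers with 0 of 6 called (0.00188, kept with an estimated correlation), and JNK genes with 1 of 19, Jra (0.11) (0.00255, and 0.0865 with an estimated correlation). Oxidative stress genes had 1 call of 37, GstE7 at 0.19 (0.00485, and 0.24 with an estimated correlation), small RNA genes 1 of 11 (0.00457, and 0.1 with an estimated correlation), and autophagy genes 0 of 19 (0.00937, and 0.454 with an estimated correlation). Lower as lists were oxidative phosphorylation with 2 of 71 called, ND-B14.5B (-0.10) and ND-ACP (-0.09) (3.24e-09, and 0.296 with an estimated correlation), cell cycle with 0 of 18 (6 lower and 1 higher adjusted over the list alone; 2.18e-08, and 0.24 with an estimated correlation) and ribosomal proteins with 0 of 34 (2.37e-05, and 0.489 with an estimated correlation). Plasmatocyte markers passed only through eater (camera adjusted p = 2.45e-04): the other 11, with a median of -0.04, did not pass, nor did the 27 phagocytic receptors other than eater.

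Within single conditions, eater, Sec24AB and Hem were called lower in all 4, Stam was called lower in 3 and eIF4A was called higher in the 3 with bacteria. Without bacteria 11 features were called (6 higher, 5 lower), which also included form3, Ogg1 and GlcAT-S, named here after their values were seen. With bacteria 14 were called at 30 min (8 higher, 6 lower), among them corto, and rdx and scu, also named after their values were seen; 5 at 90 min, eater, Stam, Sec24AB, Hem and eIF4A; and 6 at 180 min, these and Tsp42Ef. A mean intensity of at least 100 was reached by 7 of the 11 calls without bacteria and by 8 of the 14 at 30 min. Without bacteria form3 lay near the floor, at 17.6 in eater RNAi and 8.40 in control RNAi. The share that was higher in eater RNAi was 20.0% at 90 min and 33.3% at 180 min, or 0% and 58.3% with quantile normalization. With the replicate as a block the counts were 26, 72, 9 and 11; without replicate 1 they were 9, 6, 3 and 23, without replicate 2 12, 16, 3 and 4, and without replicate 3 19, 30, 9 and 20. Leaving out 1 array gave 19 (control RNAi replicate 1) and 26 (eater RNAi replicate 2) without bacteria, and 46 at 30 min (eater RNAi replicate 2). At 90 min it gave 14, 8 and 11 (control RNAi replicate 2, eater RNAi replicates 1 and 3), and at 180 min 38 and 10 (control RNAi replicates 1 and 2) and 13 and 18 (eater RNAi replicates 1 and 3).

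**Figure D4:**
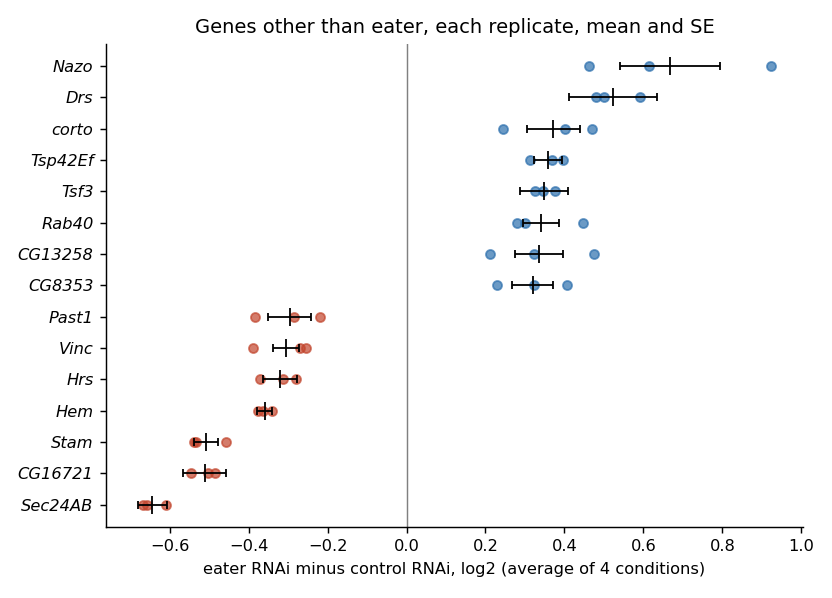
Log2 difference between eater RNAi and control RNAi, averaged over the 4 conditions, for the 15 named genes other than eater; points are the 3 replicates, vertical ticks the mean and bars the SE. The largest are Nazo at 0.67 and Sec24AB at -0.64, and each gene has 1 sign in all 3 replicates, which also served to choose the genes.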

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

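Every test of an explanation in this part was chosen after the result was seen; the counts of other splits were planned. Responses differed between the times after warming, by tests of the differences themselves. In control RNAi 679 features differed between 30 and 90 min (301 higher and 378 lower at 90 min) and 1351 between 90 and 180 min (805 higher, 546 lower); in eater RNAi the counts were 739 (357 and 382) and 1344 (789 and 555). CG14275 differed between the knockdowns in its response at every time, by -0.00462, -0.00487 and -0.00448 log2 units (limma F test, adjusted p = 8.61e-04 over the 3 times). In cells without bacteria it was 0.00487 higher in eater RNAi, at intensities of 4.75 in control RNAi and 4.82 in eater RNAi, beside the floor. All 3 differences use these cells, and with bacteria the gene was not called between the knockdowns. The calls therefore repeat 1 difference at the floor. In data outside the comparisons, 1 of 183 control probe sets, for the middle part of the actin 5C transcript, was 0.18 log2 units higher with bacteria at 30 min, averaged over both knockdowns (adjusted p = 0.00358 over the control probe sets, 5 of which had unadjusted p below 0.05).

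The summed log2 change from cells without bacteria, which joins bacteria and time, was no smaller after eater RNAi at 90 and 180 min. The tables argue against a failed knockdown, since eater was at most 6.22% of its control level in any condition. They also argue against a weakening of the summed log2 response to 80%, hidden by the few arrays, at 90 and 180 min. There the mean ratio less 2 SD was no lower than 98.5%. At 30 min it was 69.5%, so such a weakening could have gone unseen. Whether time and warming rather than bacteria moved the later genes cannot be told apart, since cells without bacteria were taken at 30 min alone; of the 1911 features called at 180 min in control RNAi 50.3% had the same sign at 30 min in eater RNAi, which decides nothing. A response driven by other receptors, or by bacterial material that is sensed without uptake, stays among the open explanations and was not tested.

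In replicate 2, Imd targets were already higher in the cells without bacteria: pirk was at 2787 in control RNAi against at most 493 in the other replicates, and at 3148 against at most 559 in eater RNAi. Antimicrobial peptide and Imd genes stood at a median of 24.7% (10 genes, 9 highest in replicate 2) and 26.3% (9 of 9) of the way to their 30 min level. RNA or cells of a sample with bacteria would have moved JNK genes as far, but their median was 0.732% in control RNAi (5 genes, 0 highest in replicate 2) and 5.80% in eater RNAi (6 genes, 5 highest), and with a 180 min sample the share would have ranged from 0.144% for AttD to 30.2% for pirk. Scaling of the arrays is argued against by median shifts of no more than 0.0168 log2 units. An immune activation of that experiment's cells before bacteria were added, shared by both knockdowns (26.3% in eater RNAi), stays open, and no group in the design tests it.

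Genes other than eater differed between the knockdowns, among them Sec24AB, Stam, Hem and Hrs. Scaling as the whole cause is argued against, since 13 of the 15 named genes passed under quantile normalization (median centring moved almost nothing and tests little); Drs went from 0.52 to 0.48 (adjusted p = 0.0532) and CG13258 from 0.34 to 0.29 (adjusted p = 0.0999). A difference in 1 of the 3 experiments alone was tested by holding out each replicate; over all called features 72.2%, 55.6% and 91.6% kept their direction, and the test was then limited, after this was seen, to mean intensities of at least 100, where 11 of 11, 5 of 5 and 342 of 367 (93.2%) did; the median size over all called features went from 0.17 to 0.15, 0.20 to 0.16 and 0.15 to 0.07 in the replicate left out. Action of the eater dsRNA on other transcripts stays open: 27 of 28 lower features other than eater were lower in all 4 conditions, as were 65 of 70 higher ones higher, which loss of eater would give as well. A second dsRNA against another part of eater could separate these.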

How the results depend on the processing

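The replicate block, the scalings and the other settings were planned; leaving out features with 1 value on all arrays, alone or with the block, and leaving out the no-bacteria arrays of replicate 2 were chosen after seeing the data. No result for a named gene reversed. These results number 492, each 1 gene in 1 comparison, and include eater also where it was not called. All 492 stayed as they were with the replicate block, the random block, no filter, median centring and log2 of the value plus 64. With plus 1 it was 490, with every probe set 491 and with quantile normalization 472. Without replicate 1, 2 or 3 it was 280, 259 and 406, with trend and robust moderation 195 and with only the groups compared 196. Unless stated, the cause was not tested; stricter thresholds lower counts by construction. Counts are given in the order response at 30, 90 and 180 min in control RNAi, the same in eater RNAi, the average of eater RNAi against control RNAi, and that difference without bacteria and with bacteria for 30, 90 and 180 min. The replicate block gave 775, 2210, 2858, 992, 2870, 2584, 583, 26, 72, 9 and 11, and 154 list calls in place of 123, and changed no other call of a named gene; the random block gave 158 on average and 19 without bacteria, and lists were not tested with it. Trend and robust moderation gave 56, 198, 283, 54, 212, 268, 4, 2, 3, 1 and 1. Only the groups compared gave 62, 386, 507, 20, 363 and 592 for the responses, 2, 1, 1 and 1 for the single conditions, and 0 for the differences of response at 30 and 90 min. At least 2-fold gave 55, 114, 181, 53, 133, 186, 1, 1, 1, 1 and 1, and 0 for the 3 differences of response. Adjusted p under 0.01 gave 852 and 1258 at 90 and 180 min in control RNAi, 234, 1109 and 1116 in eater RNAi, 32 on average, 6 without bacteria and 7 at 30 min. The 60th percentile filter gave 149 on average, 9 at 30 min and 11 at 180 min, and quantile normalization 12 at 180 min. With both of these, and with constant features left out, the differences of response at each time and at any time had 0 calls in place of 1. Constant features left out with the replicate block gave 885, 2393, 3057, 1178, 3084, 2749, 750, 37, 125, 10 and 14, and 0 differences. Without the no-bacteria arrays of replicate 2 the average gave 53, the difference without bacteria 26, the differences of response 8, 8, 8 and, at any time, 6. Without single arrays or replicates the ranges were 109 to 523, 423 to 1561, 695 to 1941, 102 to 463, 589 to 1976, 555 to 1911, 10 to 392, 9 to 26, 6 to 46, 3 to 14 and 4 to 38, and for the differences of response at 30, 90, 180 min and any time 1 to 16, 1 to 8, 1 to 12 and 1 to 16. List calls were 31 with an estimated correlation, 85 with fry, and 99 to 147 without a replicate. Of the 123 list calls, 107 were kept with median centring, 109 with quantile normalization and 109 with constant features left out. The 60th percentile filter kept 87 of the 120 that could be tested. Reversed lists were ribosomal proteins in eater RNAi against control RNAi at 30 min with quantile normalization (adjusted p = 0.958) and at 180 min without the 180 min control array of replicate 3 (0.845; leaving out others gave 5.36e-05 and up), and oxidative phosphorylation, difference of response at 180 min, without the no-bacteria control array of replicate 3 (0.953; leaving out others gave 8.36e-04 and up). A floor on log values was not run, since the values are linear. The number of arrays limits precision, and intensities near the floor hold little signal.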

Other observations

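The tests of single genes and lists were planned and the comparison of replicates was chosen after the result was seen. Much of the first wave of transcription was transient. Of 356 features higher at 30 min in control RNAi, 188 were lower at 180 than at 30 min and 32 were higher, and 32 lay below the level without bacteria at 180 min; since the same 30 min arrays served to choose them, the arrays of the other knockdown are the fairer test, in which 157 were lower and 54 higher. For features higher at 30 min in eater RNAi the counts in control RNAi arrays were 160 lower and 23 higher of 282. Between 30 and 180 min in control RNAi puc fell by 1.99 ± 0.09 (adjusted p = 3.08e-10), Ets21C (-2.44 ± 0.31), Jra (-0.59 ± 0.04), Tollo (-1.22 ± 0.09) and cbt (-0.89 ± 0.13) fell as well, and AttD (5.61 ± 0.33), DptB (5.35 ± 0.25) and PGRP-LB (5.19 ± 0.18) rose. For Rel (0.07 ± 0.16) and pirk (-0.29 ± 0.79) no such change passed. In eater RNAi puc (-1.84 ± 0.09) and Ets21C (-2.46 ± 0.31) took the same course.

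Between 30 and 180 min the chaperone gene DnaJ-1 went from below to above its level without bacteria (1.22 ± 0.09, adjusted p = 1.10e-07); l(3)72Dn (0.74 ± 0.05) and Mcm2 (0.53 ± 0.08) rose over this interval, while spin (-1.14 ± 0.08), dl (-0.59 ± 0.07) and Tret1-1 (-1.46 ± 0.14) fell. Oxidative stress genes rose in 7 and fell in 5 of 37 at 180 min in control RNAi (camera adjusted p = 0.998), with GstD3 (0.73) and GstD1 (0.50) up and Cat (-0.79) and cnc (-0.70) down. Autophagy genes rose in 4 of 19 at 90 min (camera adjusted p = 0.127), led by Atg18b (0.99). Coagulation genes rose in 5 and fell in 1 of 22 at 180 min (0.423), with Spn28Dc at -0.82 and Hml at 0.72. Proteasome genes went both ways, with Rpn6 at 0.44 and Rpn8 at -0.22 (0.148). Ribosomal protein genes had 1 call, RpLP0 at -0.10 (0.705). Fat body and muscle markers had 0 calls at 30 min in control RNAi (0.782 and 0.753), and germ line markers rose in 1, osk (1.03), and fell in 1, tej (-0.72), of 6 at 180 min (0.991).

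Replicate 3 stood apart from the others in all groups. In all 8 groups 1327 features had replicate 3 on the same side of both other replicates (698 higher), which chance gives 0.0305% of features. Mean intensities in replicate 3 and in the others were 2551 and 503 for MFS3, 206 and 33.6 for Cyp4p1, 42.9 and 171 for GstD7, and 445 and 130 for c(2)M, chosen after their values were seen. In all 8 groups replicate 3 also had the lowest 3' to 5' ratios for GAPDH and eIF4A, though in no group for actin. For eIF4A in eater RNAi without bacteria the ratio was 2.24, against 3.07 and 2.99 in replicates 1 and 2. In control RNAi at 90 min it was 2.874, against 3.271 and 2.876. Whether RNA quality or labelling set this replicate apart was not tested.

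Other splits of the arrays were counted for each result. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the responses in control RNAi 1 split, the real one, gave as many calls: 446 at 30 min against at most 3 in another split, 1359 against 2 at 90 min and 1911 against 2 at 180 min. In eater RNAi it was also 1, with 464 against 2, 1848 against 1 and 1721 against 1. For eater RNAi against control RNAi it was 1 without bacteria (11 against 2) and 1 at 30 min (14 against 12). At 90 min 2 splits gave as many, since control RNAi replicates 1 and 3 with eater RNAi replicate 3 gave 24 against the real 5, which points to a structure of the samples along the replicates; among the 4 splits that part as many pairs the highest other was 1, and the replicate block gave 9 calls. At 180 min 2 splits gave as many, with 6 against 6 for control RNAi replicate 1 and eater RNAi replicates 2 and 3, a split that parts as many pairs as the real one. For the average of the 4 conditions 1 of 100 splits gave 99 calls, the real one, against at most 11. Among 100 splits that exchange the knockdowns only within replicates, which keep the pairing, the highest other was 4. Both kinds of split exchange arrays separately in each condition, although a replicate set was processed together. They therefore do not show how often chance among 3 experiments would give such a count. For the differences of response, with 1 call each, 46, 49 and 39 of 100 splits gave as many at 30, 90 and 180 min. At any time 64 did, and the highest counts were 48, 31, 12 and 8. Splits that exchange the knockdowns only within replicates gave up to 24, 18, 23 and 11. An exchange in 1 condition alone turns a steady difference, such as that of eater, into a difference of response. These splits therefore cannot tell how often chance would give 1 call, and chance is not excluded.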
